A study of Mus musculus with 2 samples.

How the data were processed

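The series holds 2 libraries from mouse astrocytes that were grown from neural stem cells of the wild-type strain C57BL/6J. One library is a chromatin immunoprecipitation (ChIP) with an Abcam antibody against the histone demethylase PHF8, and the other is the input, sonicated chromatin sequenced without the antibody step. Each of these groups has 1 library, so no value has a replicate check, and every comparison is one of 2 libraries, not of conditions.

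Per the submitters' processing notes, reads were aligned with Bowtie2 to the mouse genome build mm10. The aligner's version and its read filters are not given in the sources used here. The names of the deposited tracks carry a p setting of 0.001, and the form of their values is that of MACS tracks, whose version is not given in the sources used here. The deposited ChIP track is a pileup signal: whole numbers of overlapping reads, each 49 bp long, with 0 non-whole values and a maximum of 98, the height that 1 read per position and strand allows. Reads were not extended to fragment length, since 99.4% of the isolated single-read stretches had exactly 49 bp. The deposited input track is a local background signal scaled to the ChIP depth: at each position it holds the largest of the scaled read pileup, wider local averages and a genome-wide floor of 0.600, and 56.1% of positions lie at that floor. Because it takes a maximum, this background lies above the true input coverage over most of the genome, so a ratio of pileup to background falls below 1 where nothing is enriched.

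The whole-read pileup of the input was recovered from the background track by dividing it by its scaling step of 0.988. Positions where a local average hides the pileup made up 0.467% of the main chromosomes. They were set to the mean of a Poisson law with the local average as its rate, cut at the highest pileup possible there. The lower and upper limits were used as alternatives. This gave 23.2 M input reads, 100.04% of the number implied by the scaling step. On simulated tracks it returned 99.9% of the true reads. Read ratios between ChIP and input were divided by 0.988, the ratio of the 2 libraries over the main chromosomes, with exact Clopper-Pearson 95% intervals of the ChIP share of reads. All intervals cover counting error only. The ChIP depth of 8.93 reads per kb on the autosomes limits single windows: a window of 1 kb around a gene end held a median of 11.6 ChIP reads.

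Enriched regions were scored as the −log10 Poisson p of the ChIP pileup given the deposited local background. Positions with a score of at least 5 were merged over gaps up to 100 bp and kept when they spanned at least 200 bp and had a summit of at least 2 times the background. Chromosomes 1 to 19, X and Y were used. Gene positions came from a RefSeq gene table on the same assembly, without strand, transcript starts or exons. A promoter therefore means here the 500 bp either side of either end of a gene, and each gene takes its end with the higher value, which raises the values of all genes by selection. Of the genes on the main chromosomes, 346 with coordinates before the first read of their chromosome were left out, on the assumption that these are positions on other contigs. That left 49597 genes, of which 21776 are protein-coding and 21771 could be measured. The promoter value is log2((mean pileup + 1)/(mean background + 1)) over 1 kb, with a pseudocount of 1. A gene would be called enriched when an enriched region lay within 500 bp of an end.

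The 23 gene lists cover astrocytes, neural stem cells, other cell types of the brain, the cell cycle, core cell functions, chromatin regulators and signalling pathways, with a list of silent tissue-restricted genes as negative control, and 544 of their 546 symbols were matched. For each list, the median promoter value was placed as a percentile among 10000 random lists of the same size matched on the tercile of background, as a description of these libraries. That matching shares input reads with the denominator of the value, so percentiles without matching, and matched on reads of both libraries in the flanks, were added. The gene lists, the scoring rule, the percentile and the alternatives called planned were chosen before the data were examined. So was the rule for named genes: the 25 highest promoters among the genes called enriched, the 3 highest and 2 lowest members of each list, Phf8 itself, and the 5 best enriched regions far from genes. With 0 genes called and 0 regions, only the list members and Phf8 follow from it, and a few list members are not reported here; other genes were named after their values were seen. The window of 500 bp inside the gene, its comparison with flanks 3500 to 4500 bp from the ends on both sides, and the pooled reads per list were chosen after the read profile had been seen. The spread of a pooled ratio over all genes is a jackknife over chromosomes.

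The steps were tested on simulated data. Implanted 500 bp regions at 10 times the background were found in 45%, at 15 times in 97.5% and at 20 times in 100% of 40 cases, and at 5 times in 0%. Outside these regions the simulated ChIP had a mean pileup of 0.600, equal to the floor, against 0.438 in the real ChIP on the autosomes. These shares can therefore be too high for the real tracks. A list of 25 genes whose reads inside the ends were raised 1.2-fold left the middle 95% of random lists upward in 54% of draws, and 1.3-fold in 88%. For the promoter value, a 1.2-fold rise gave 79%, and no rise gave 3%; these shares vary by chance between draws. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

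Alternatives covered the score threshold, minimum fold, length and gap, a flat background, the pseudocount, the promoter window, the matching of random lists and the recovered input reads. Motifs, CpG content and exon or intron classes were not analysed here, since they need a genome sequence or exon positions. The same holds for an analysis of 5 prime ends alone, which needs the strand.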

Results

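PHF8 binding to chromatin was measured in astrocytes, the star-shaped support cells of the brain, grown from neural stem cells of wild-type C57BL/6J mice. PHF8 is a histone demethylase that removes repressive methyl groups from histones H3 and H4 and holds on to methylated H3 at active gene starts through its PHD finger; its gene is mutated in an X-linked form of intellectual disability. The data are 1 ChIP library of 22.9 M reads and 1 input library of 23.2 M reads. The question is where on the genome PHF8 chromatin was enriched over input. With 1 library per group there is no replicate check, so all ratios and scores compare these 2 libraries only.

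At this depth no place in the astrocyte genome rose above the local background as an enriched region, and no gene was called bound. Genes of astrocyte identity, neuronal genes, cell cycle genes and the Phf8 gene itself were all without a called region. The ChIP and the input tracks had nearly the same distribution of read pileup: 67.6% of positions had no ChIP read and 67.1% no input read, and a pileup of at least 7 covered 51.8 kb in the ChIP and 42.2 kb in the input. Hidden input positions, 0.467% of the main chromosomes, are left out of the input figures, while the ChIP figures hold all positions. They lie where a local average exceeds 1 read, so the difference at high pileup can come from this alone. The autosomes had ChIP to input ratios between 0.993 and 1.01, and the X chromosome had 1.019 (95% interval 1.016 to 1.022).

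**Figure D1:**
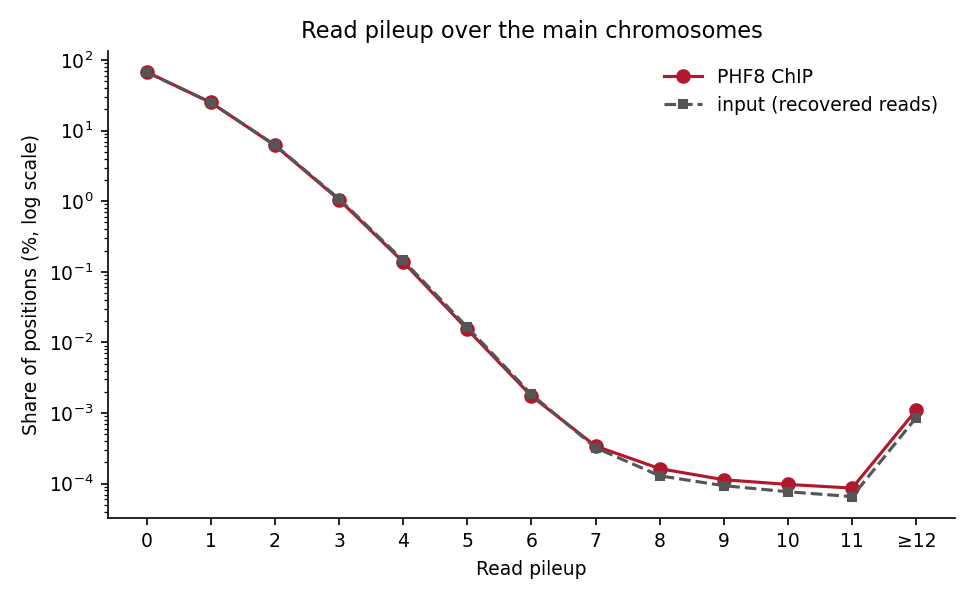
Share of positions on the main chromosomes (%, log scale) at each read pileup, for the PHF8 ChIP (circles) and the recovered input (squares), 1 library each. The lines lie close together from 67.6% and 67.1% of positions without a read down to the highest pileups, where the ChIP covers more positions. Hidden input positions are left out of the input line, which can by itself give that difference.

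The count of enriched regions was 0 at a score of at least 5, and 0 of 21771 measured protein-coding genes were called. Regions at 10 times the background over 500 bp were found in 45% of simulated cases and regions at 5 times in 0%, so weaker binding was not detectable by this rule. The simulated reads were denser than those on the autosomes, so the real share found can be lower. At a score of 3 there were 2 regions, on chromosome 13 from 3373088 to 3373300 and on chromosome 14 from 19417355 to 19417588 (mm10), named after their values were seen. Both lay in sequence with a background of 13 and 27.7 reads, more than 3 times the genome median, and neither was at a gene end. A rule with no minimum length, chosen after the data were seen, gave 254 short stretches. In 20000000 simulated positions the same rule gave 5 stretches outside the implanted regions, which is more per Mb than 254 over 2722 Mb. The simulated read density was above that of the autosomes, so these rates are not like for like. The count of 254 alone thus shows no excess over chance. Of the 254 stretches, 19 touched an end of a protein-coding gene, where random placement gave a mean of 3.89 and a range of 0 to 10. These 19 stretches marked 21 protein-coding genes. Placement covered whole chromosome lengths and was not matched on coverage. Stacks of at least 6 input reads with at most 1 ChIP read also exceeded such placement inside these ends, with 77 against 35.7. An excess over this placement is therefore not particular to the ChIP. At a score of 3 with no minimum length the ratio to random placement was smaller, with 606 stretches at ends of protein-coding genes against 344 (294 to 395). Among the 21 genes were Snrnp40, which encodes a protein of the U5 small nuclear ribonucleoprotein, the exosome subunit gene Exosc8, the mitochondrial ribosomal protein gene Mrpl15 and Pkm, the gene of pyruvate kinase in glycolysis.

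Just inside the ends of protein-coding genes the ChIP library held slightly more reads than the input. In the 500 bp inside 43510 gene ends the pooled ratio was 1.027 (1.021 to 1.033), against 0.953 (0.948 to 0.959) in the 500 bp outside. Relative to flanks 3500 to 4500 bp away the inside ratio was 1.0335 ± 0.0039 (SE, jackknife over chromosomes), and it lay above 1 on 21 of 21 chromosomes. That window was chosen after the profile was seen, and over 1000 bp inside the ends the ratio was 1.0098 ± 0.0027. The ChIP was at 1.1 and the input at 1.07 times its own flanks inside the ends, and outside them they were at 1.05 and 1.1. Ends of long non-coding RNA genes had 0.989 ± 0.0041 relative to flanks and tRNA genes, which RNA polymerase III transcribes, had 0.969 ± 0.021. Small nucleolar RNA genes had 1.05 ± 0.019, microRNA genes 1.05 ± 0.018, pseudogenes 1.02 ± 0.0073, and the olfactory and vomeronasal receptor genes, which are silent outside sensory neurons, 1.04 ± 0.016. In the 500 bp outside, small nucleolar RNA genes were at 1.04 and microRNA genes at 1.03 of their flanks, so their higher ratio is not confined to the inside. Windows were not cut at the other end of a gene, so in short genes the inside window runs past it. Over the 1 kb on both sides of an end, pileup over deposited background relative to flanks was 1.04 ± 0.0040, but with recovered input reads in place of that background it was 0.996 ± 0.0031, within 2 SE of 1.

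**Figure D2:**
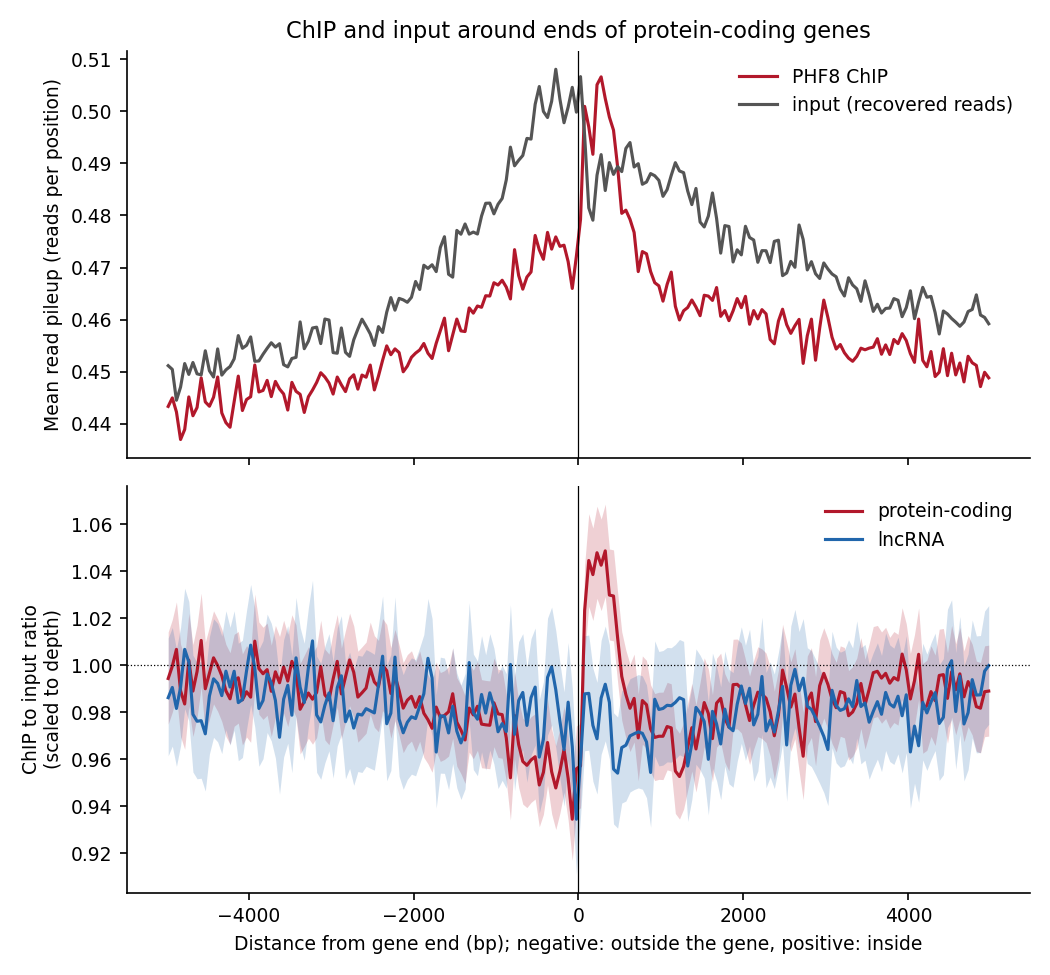
Mean read pileup (upper panel, reads per position, axis not from 0) of ChIP and recovered input in 50 bp bins around the ends of protein-coding genes, and the depth-scaled ChIP to input ratio (lower panel) for protein-coding and long non-coding RNA genes with 95% counting intervals as bands. Negative distances (bp) lie outside the gene; the ratio at protein-coding genes reached 1.05 inside the end and 0.935 just outside.

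Single gene ends with far more ChIP than input reads were few. At a binomial score (−log10 p) of at least 3 for the 500 bp inside, 27 ends were higher in the ChIP and 6 were lower, where counting error alone would give 10.8 and 8.53. On simulated reads this score found 48% of ends raised 4-fold, 2.5% of those raised 2-fold and 0.5% of those raised 1.5-fold. It also called 7 to 14 unchanged ends. A small number of called ends therefore does not mean that few ends were raised. In windows 4 to 4.5 kb inside the same genes 18 ends were higher and 11 lower, against 10.1 and 7.46 from counting error. In windows 4 to 4.5 kb outside 10 were higher and 4 lower, against 9.87 and 7.05. Over the 1 kb around the end both directions were in excess, with 45 higher and 35 lower against 17.2 and 19, and in the 500 bp outside there were 11 and 14 against 10.9 and 8.39. Ends inside genes are named here after their values were seen. The highest was at Qdpr, which encodes dihydropteridine reductase, with 16 ChIP reads and 0.367 input reads (chromosome 5, 45450229). It was followed by Exosc8 with 17.5 against 1.08, the Mediator subunit gene Med9 with 19.8 against 2.08, and Dlat of the pyruvate dehydrogenase complex with 15.7 against 1.47. The histone demethylase genes Kdm5a (12 against 0.347) and Kdm4b (15 against 1) and the DNA methyltransferase gene Dnmt3a (10.9 against 0.163) were also among them. The lower ends were at Calcrl, Ints8, Klf10, Tia1, Golga3 and Rnf169, with 0 to 3.41 ChIP reads and 11.6 to 18.2 input reads.

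Promoter values were low for nearly all genes. The median log2 value was −0.25, with quartiles of −0.37 and −0.13, and 1692 of 21771 genes (7.77%) lay above 0; the deposited background is a maximum and pushes this value down. Where coverage is low, a gene can have a low value without fewer ChIP reads: Pgk1 had −0.43 with 4.18 ChIP reads and 1 input read, Sox3 −0.43 with a ratio of 1.26 (0.272 to 6.37) and Trem2 −0.39 with 1.54 (0.360 to 7.31). Values of single list members rest on few reads. Gja1, with −0.61, had a ratio of 0.422 (0.093 to 1.40), and Hoxc4, with −0.068, had 4.10 (1.09 to 22.4). The sign of a single value thus does not tell more from fewer ChIP reads. Phf8 (chromosome X, 151520641) had −0.26, near the median, from 10 ChIP and 8 input reads, a ratio of 1.26 (0.449 to 3.69). The highest value, 0.52, was at Ankle2, a gene of nuclear envelope reassembly after mitosis, with 34.0 ChIP and 9.35 input reads and a ratio of 3.68 (1.80 to 9.06). The protease gene Nrd1 had 0.49, the endosomal sorting gene Pdcd6ip 0.45, the taurine synthesis gene Csad 0.45, the RNA-binding gene Rbm33 0.46, Snrnp40 0.44 and the splicing gene Wbp11 0.41. BC049715 (0.48), Zcchc17 (0.44), Lmbr1 (0.43) and Ykt6 (0.42) also lay above Wbp11. The window of Snrnp40 overlaps that of Zcchc17, and the window of Wbp11 that of BC049715, so these reads cannot be assigned to one gene. These high genes were named after their values were seen, and as the best of 21771 their ratios are inflated by selection.

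Among the gene lists, those of the spliceosome and of the mitochondrial respiratory chain stood highest. Spliceosome genes, which encode the machinery that removes introns, had a median promoter value of −0.14, at percentile 99.8 of random lists, and 18 of 25 lay above the median of all genes. Srsf7, a splicing factor, was the highest with 0.40, from 31.2 ChIP and 12.6 input reads and a ratio of 2.5 (1.23 to 5.02); Snrpd3 had 0.28 and Sf3b1 0.20, while Hnrnpk and Srsf1 were lowest with −0.45 and −0.56. Respiratory chain genes had a median of −0.16 at percentile 99.2, with 20 of 27 above the median of all genes. Ndufb3 of complex I had 0.21, Cox5b 0.026 and Uqcrfs1 0.021, and Ndufv1 and Uqcrc1 had −0.46 and −0.48. These were 2 of 23 lists outside the middle 95% of random lists, where chance would give 1.15. The respiratory chain list left that outer range in 3 of 9 settings, with percentile 90.2 for recovered input reads, 92.7 for these inside the ends and 92.6 over 2 kb. The spliceosome list stayed at percentile 98.9 or above in all 9 settings.

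With reads pooled over the 500 bp inside the ends, spliceosome genes again led, and 3 of 23 lists lay outside the middle 95% of random lists matched on flank reads: the spliceosome, Hox and oligodendrocyte lists. Matched on background there were 5: the spliceosome, respiratory chain (percentile 99.7), cytosolic ribosomal (99.5), histone demethylase (98.5) and oligodendrocyte (1.63) lists, with Hox genes inside at 2.67. Spliceosome genes had a ratio of 1.33 (1.14 to 1.55), at percentile 99.8 of random lists matched on flank reads, with more ChIP than depth-scaled input reads in 20 of 25 genes, and their flanks had 0.980 (0.903 to 1.07). Histone demethylase genes followed with 1.23 (1.01 to 1.49, percentile 96.2), synapse genes with 1.2 (1.02 to 1.41, percentile 96.2) and respiratory chain genes with 1.17 (1.02 to 1.37, percentile 93.9). The lowest were the Hox genes, which pattern the body axis, with 0.832 (0.684 to 1.01, percentile 1.90), and the oligodendrocyte genes with 0.817 (0.665 to 1.01, percentile 1.89).

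**Figure D3:**
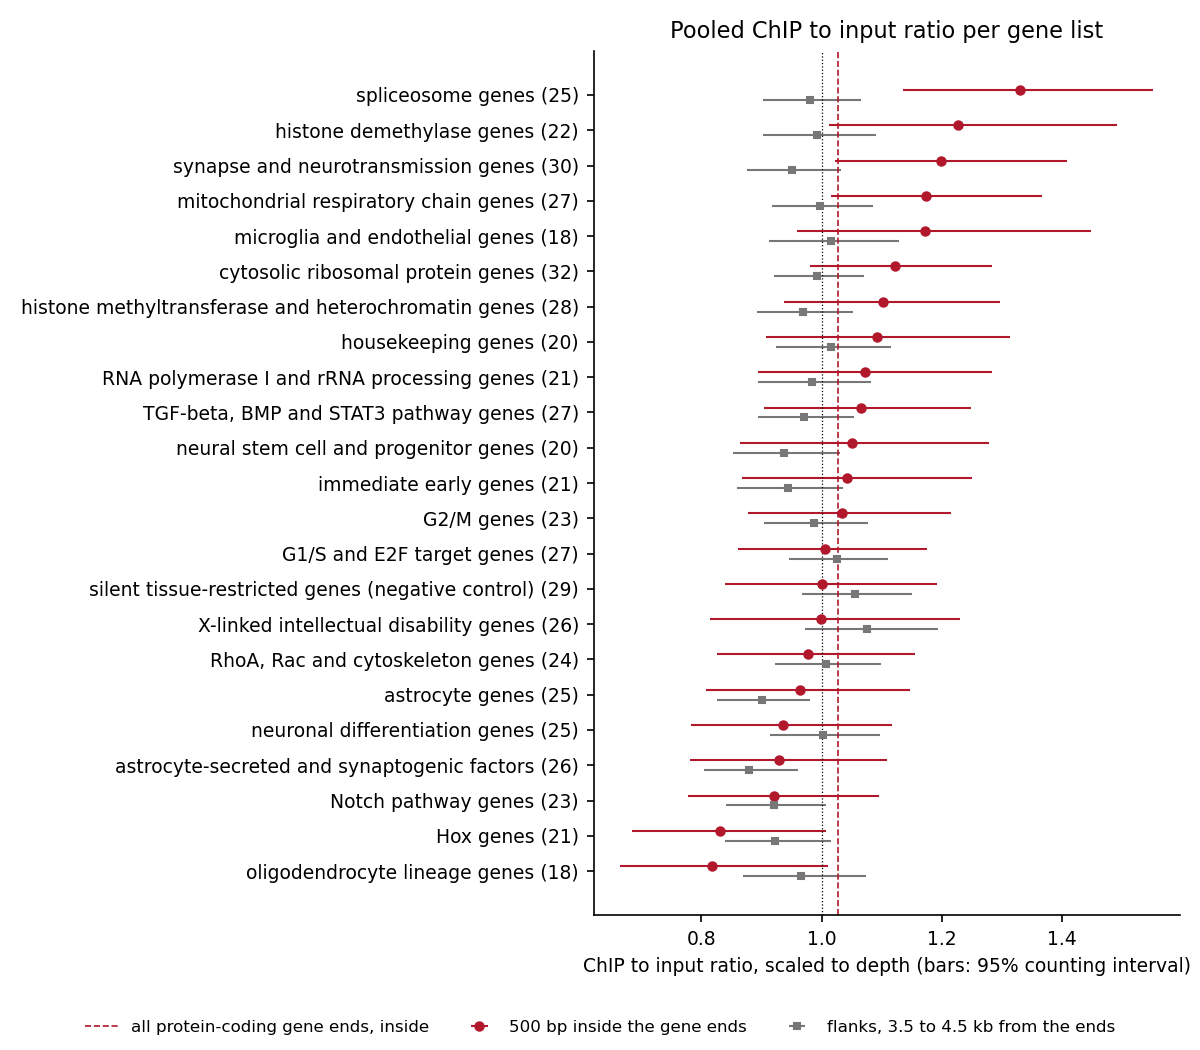
Depth-scaled ChIP to input ratio of reads pooled over each gene list (number of genes in brackets), in the 500 bp inside the gene ends (circles) and in flanks (squares), with 95% counting intervals, 1 library each. Spliceosome genes lie at 1.33 inside the ends and 0.980 in the flanks; the dashed line marks all protein-coding gene ends at 1.03.

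Genes of brain cell types lay within the middle 95% of random lists by the promoter value with a pseudocount of 1. Oligodendrocyte genes left it at percentile 0.97 with a pseudocount of 0.1 and at 1.66 when matched on flank reads, and microglia and endothelial genes at 98.4 with recovered reads inside the ends. Astrocyte genes had a median of −0.27 at percentile 34.5, with 12 of 25 above the median of all genes, and their flanks had a low read ratio of 0.901 (0.826 to 0.981, percentile 2.37); the glutamate transporter gene Slc1a3 had −0.017, Gjb6 −0.064 and Fgfr3 −0.090, and the transcription factor gene Nfia −0.50 and the gap junction gene Gja1 −0.61. Neural stem cell and progenitor genes had percentile 34.1, from −0.0092 at Notch2, −0.040 at Zbtb20 and −0.10 at Gli2 down to −0.41 at Lhx2 and −0.43 at Sox3. Astrocyte-secreted and synaptogenic factors had percentile 12.8 and flanks at 0.880 (0.805 to 0.961, percentile 0.46), with Sparc at 0.088, Nrxn3 at 0.0067 and Nlgn2 at −0.069, and with Thbs2 at −0.47 and Tgfb1 at −0.57. Synapse and neurotransmission genes had percentile 95.7; the postsynaptic scaffold gene Homer1 had 0.30 from 24.8 ChIP and 6.86 input reads, Vamp2 0.18 and Rims1 0.030, and Cplx1 had −0.42 and Syn1 −0.50. Neuronal differentiation genes had percentile 47.0, with the neurofilament genes Nefl at −0.019 and Nefm at −0.073 and Tbr1 at −0.051, and with Elavl3 at −0.40 and Neurod2 at −0.52. Oligodendrocyte lineage genes, for the myelin-forming cells, had percentile 3.71; Cnp had 0.099, Opalin −0.029 and Ugt8a −0.070, Enpp6 −0.48 and Olig2 −0.53. Microglia and endothelial genes had percentile 95.4, with the vessel genes Cdh5 at −0.034, Pecam1 and Tek at −0.058 and −0.059, and Trem2 at −0.39 and Flt1 at −0.56.

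Cell cycle lists, and core function lists other than the spliceosome and respiratory chain, were also within that range in this setting. Cytosolic ribosomal protein genes left it in 4 of 9 settings, at percentile 98.6 with a pseudocount of 0.1, 99.4 over 2 kb, 97.6 with recovered reads and 99.7 on a flat background; RNA polymerase I genes (99.5) and housekeeping genes (99.8) left it on a flat background. Genes of G1/S and E2F targets, which prepare DNA replication, had percentile 78.2; Ccne2 had 0.0066 and Ccnd2 −0.030, and E2f1 had −0.45 and Ccnd1 −0.52. Mitotic genes of G2/M had percentile 34.3, with the kinase genes Aurka at 0.27, Cdk1 at 0.028 and Plk1 at −0.058, and Cenpa at −0.38 and Smc2 at −0.41. RhoA, Rac and cytoskeleton genes had percentile 92.5, from Cfl1 at 0.15, Arpc2 at 0.057 and Pfn2 at 0.0010 to Rock1 at −0.46 and Arpc3 at −0.57. Cytosolic ribosomal protein genes had percentile 96.8, with 24 of 32 above the median of all genes; Rps27 had 0.21, Rpl30 0.11 and Rps6 0.073, and Rpl8 had −0.42. RNA polymerase I and rRNA processing genes had percentile 84.2, with Bop1 at 0.20, Polr1b at 0.077, Fbl at 0.023, Npm1 at −0.32 and Nop2 at −0.48. Housekeeping genes had percentile 73.5; the proteasome gene Psmb4 had 0.21, Eef1a1 0.063, Rab7 0.060, Pgk1 −0.43 and Hprt −0.45.

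Chromatin regulators, signalling genes and silent genes gave no list outside the middle 95% in this setting either. In others, X-linked intellectual disability genes were at percentile 1.84 (pseudocount 0.1) and 0.45 (flat background), and TGF-beta, BMP and STAT3 genes at 98.6 (2 kb) and 98.2 (flat background). Notch genes (97.96) and histone methyltransferase genes (98.5) left it on a flat background. Histone demethylase genes had percentile 22.7 over the 1 kb window, although Riox1, a gene of a nucleolar histone demethylase and hydroxylase, had 0.33 with a ratio of 4.00 (1.61 to 12.1), Kdm4b 0.14 and Kdm5a 0.13; Kdm2b had −0.53 and Kdm6a −0.56. Histone methyltransferase and heterochromatin genes had percentile 87.1, with Ehmt1 at 0.13, Cbx5 at 0.12, Dnmt3a at 0.10, Suv39h1 at −0.44 and Kmt2a at −0.66. X-linked intellectual disability genes had percentile 5.20, but 22.98 when matched on flank reads, and read coverage of the X chromosome was 0.576 of that of the autosomes in the ChIP and 0.565 in the input. Their values ranged from Pak3 at 0.099, Upf3b at −0.030 and Ogt at −0.045 to Syn1 at −0.50 and Rps6ka3 at −0.56. Notch pathway genes had percentile 92.4, with Notch2 at −0.0092, Dll4 at −0.022, Dll1 at −0.49 and Jag2 at −0.49. Genes of the TGF-beta, BMP and STAT3 pathways, which drive astrocyte formation, had percentile 74.2; Tgfbr2 had 0.084, Skil 0.051 and Tgfbr1 −0.040, and Stat3 had −0.51 and Smad4 −0.57. Immediate early genes had percentile 77.2, with Btg2 at 0.13, Jund at 0.047, Myc at −0.062, Klf2 at −0.51 and Klf6 at −0.53. Silent tissue-restricted genes, the negative control, had percentile 77.0, with Opn1sw at 0.041, Krt14 at 0.0021, Ckm at −0.042, Ins2 at −0.46 and Amy2a5 at −0.62. Hox genes had percentile 19.4, with Hoxa10 at 0.052, Hoxc4 at −0.068, Hoxc8 at −0.11, Hoxb4 at −0.54 and Hoxa5 at −0.56. No list had a called member by the fixed rule, and 24 list members were called, among 666 protein-coding genes, at a score of 3 with no minimum length.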

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

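The tests on the mitochondrial genome and the limits of hidden positions for the contigs were chosen after the result was seen.

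Outside the main chromosomes, 29 contigs had at least 100 ChIP reads. On 9 of them the whole counting interval of the ChIP to input ratio lay above 1, where chance would give 0.725, and on 5 it lay below 1, the mitochondrial genome included. The ratio was 1.24 on a contig of 169460 bp, 1.27 on one of 153338 bp, 1.19 on one of 950135 bp, 1.27 on one of 39963 bp, 1.21 on one of 71903 bp, 1.48 on one of 25658 bp, 1.26 on one of 55641 bp, 1.31 on one of 24277 bp and 1.25 on one of 21211 bp. With hidden input positions at their upper limit 7 of these remained: the ratio was then 1.09 (0.997 to 1.196) on the contig of 39963 bp and 1.17 (0.954 to 1.44) on that of 21211 bp. With hidden positions at 0 the interval lay below 1 on 2 contigs in place of 5, the mitochondrial genome among them. The contigs of 113677, 23573 and 28396 bp then turned, with 8803 ChIP against 6072 input reads, 994 against 665 and 356 against 290. Their direction thus depends on the hidden positions. No other explanation was tested for these contigs.

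The mitochondrial genome, which carries no histones, stood at the other end: 3412 ChIP reads against 23391 recovered input reads, a ratio of 0.148 (0.142 to 0.153). The limit of 1 read per position and strand does not explain it, since the ChIP pileup there reached 35 and the limit lies at 98; the input did reach the limit, so it lacks reads that would lower the ratio further, and 48.5% of its positions were hidden, so the interval understates the error. Input reads hidden in the deposited background do not explain it either: with every hidden position at 0 the ratio was 0.230 (0.221 to 0.239). A loss of DNA without histones in the antibody step is the biological reading the design gives, as a hypothesis. A different content of mitochondria in the starting material cannot be told apart from it, since the ratio of 0.148 rests on 1 input library.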

How the results depend on the processing

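Alternatives with no minimum length, recovered input reads, hidden positions at their limits or windows inside the gene were chosen after seeing the data, as were the 2 kb window, flat background and other matching where used for the lists; the rest were planned. No paired analysis was possible because each group has 1 library. No region was called at scores of 7 and 10, at 4 times the background, with no minimum fold, at 500 bp or without high-background regions. The count was 2 at score 3, 2 at 100 bp, 7 with gaps up to 500 bp, 37 on a flat background, 254 with no minimum length and 21689 at score 3 with no minimum length. With no minimum length, 19 regions touched ends of protein-coding genes. Counting lncRNA genes and pseudogenes too, 29 genes were called, 21 of them protein-coding. No alternative set beforehand called a protein-coding gene, but the flat background called 2 lncRNA genes and 2 pseudogenes. Input reads were 23 and 23.3 M with hidden positions at 0 and at their upper limit.

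The median promoter value was −0.53 with pseudocount 0.1, −0.075 with 5, −0.20 on a flat background and −0.28 over 2 kb. It turned to 0.30 with recovered input reads and to 0.42 with these inside the ends. These settings use read counts in place of a background that is a maximum, and each gene takes the higher of its ends. What part of this caused the turn was not tested. Pooled over all 43510 ends, without that choice, the recovered read ratio of the 1 kb window was 0.990 (0.986 to 0.994). The positive median over that window is thus no ChIP excess. The profile over both sides turned from above 1 to 0.996 ± 0.0031 with recovered reads; the cause was not tested. The ratio inside ends over flanks was 1.01 over 1000 bp and 1.04 with hidden positions at 0; in the other settings run it moved by less than 2 SE, down to 1.03 with hidden positions at their upper limit. Lists outside the middle 95% were 9 on a flat background and 5 with pseudocount 0.1, and 2 or 3 otherwise; the cause was not tested. Of 184 list percentiles under alternatives, 166 stayed on their side and 18 crossed. Not run, for want of strand, exons, sequence or called regions: 5 prime ends only, matching on CpG content and on the number of starts, the CpG threshold, the motif window, summits for midpoints and promoter shares. The region rule found 45% of simulated regions at 10 times the background and 0% at 5 times. With no minimum length it found 100% at 10 times and 65% at 5 times, so the minimum length limits the rule as well as the depth. All these shares come from simulated reads denser than those on the autosomes and can be too high for the real tracks.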

Other observations

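All tests in this part were chosen after the result was seen, except that of RNA processing genes outside the spliceosome list. Its outcome was stated before its own ratio was computed, but after the spliceosome list and several related genes and families had been looked at.

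Gene families outside the fixed lists, 12 in all and picked after seeing the data, differed in their pooled ratio inside the gene ends. Members were picked by gene symbol alone. The histone set therefore also admits genes with H2- symbols, which are not histone genes. The initiation factor set holds the kinase gene Eif2ak3, and the complex I set admits assembly factor genes (Ndufaf). Mitochondrial ribosomal protein genes, for the translation machinery of mitochondria, had 1.19 (1.09 to 1.31) over 78 genes at percentile 99.9 of random lists matched on flank reads. RNA-binding motif genes (Rbm) had 1.25 (1.09 to 1.43) at percentile 99.5, and translation initiation factor genes 1.17 (1.05 to 1.31) at percentile 98.1. Proteasome subunit genes had 1.12 (percentile 89.7), the complex I set (Nduf symbols) 1.1 (85.1) and zinc finger genes (Zfp) 1.02 (37.8). Aminoacyl-tRNA synthetase genes had 0.948 (24.3), the histone set 0.991 (19.2), keratin genes 0.961 (15.7) and potassium channel genes 0.969 (11.5). Matched on background, proteasome (99.1), complex I (99.3) and keratin (0.69) genes also lay outside the middle 95%. Olfactory receptor genes went from percentile 100 matched on flank reads to 0.13 matched on background, so the rank of a family can depend strongly on the matching.

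Clustered protocadherin genes, which give neurons their surface identity, had the lowest ratio of these families, 0.852 (0.75 to 0.968) at percentile 0.13, and their flanks were also low at 0.888 (0.837 to 0.943). Windows were summed per gene, so reads at an end shared by several clustered genes were counted once for each gene. Where ends are shared, the interval is too narrow and the percentile too extreme. How many of these genes share ends was not counted. Olfactory receptor genes had 1.09 (1.06 to 1.13) inside the ends and 1.06 (1.05 to 1.08) in the flanks, so the protocadherin and olfactory receptor families both differ over wider regions. The histone set was low in the flanks, at 0.890 (0.855 to 0.925), which is also a difference over wider regions. Inside the ends it had 0.991 (0.907 to 1.083), and the inside to flank ratio was 1.11 (1.01 to 1.23). Across 251803 tiles of 10 kb, the ratio had 1.2 times the variance of counting error. Whether differences between regions gave this extra variance was not tested, and 1 library per group cannot tell it from other variance between libraries.

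Stacks of at least 6 reads in one library and at most 1 in the other gave a further view of the gene ends. Of 3666 stacks high in the ChIP, 128 lay inside protein-coding gene ends, against 29.7 (range 16 to 51) in random placements, and 55 lay just outside, against 29.6 (16 to 43). Of 4338 stacks high in the input, 77 lay inside, against 35.7 (22 to 58), and 89 lay just outside, against 35.2 (23 to 50), so stacks of both libraries were in excess on both sides.

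The higher ChIP share inside protein-coding gene ends is a small pattern with PHF8 binding near gene starts as the hypothesis the design gives. Without strand, gene starts could not be told from the other ends. Over the 1 kb on both sides of an end, the recovered read ratio was 0.996 ± 0.0031 of that in flanks. Whether the pattern inside the ends follows gene activity is open, with 1.04 ± 0.016 for silent olfactory and vomeronasal receptor genes (above 1 on 9 of 14 chromosomes) and 0.948 (0.783 to 1.15) for the silent tissue-restricted list. Counting error is argued against by the excess over flanks above 1 on 21 of 21 chromosomes. Hidden input reads are argued against too, since with every hidden position at its upper limit the excess was 1.03 ± 0.0040. A different bias of the libraries for base composition stays open: the ratio just outside the ends was 0.959 ± 0.0034 of that in flanks, so the ratio also departs from that of the flanks beside the window, and no base composition was at hand. Pull-down of open or active chromatin by any antibody stays open as well, for want of a control antibody in these data, so the pattern may be technical.

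For the spliceosome genes, the candidate explanation that PHF8 sits at genes of RNA processing remains a hypothesis. For 23 independent random lists, the computed probability that one lies as far out as this one was 8.81%, from the percentile matched on background. The percentiles matched on flank reads (98.9) and without matching (99.57) were less extreme and would give a larger probability. For the promoter value alone chance therefore stays open. Genes of RNA processing outside the list (Lsm, Prpf, Ddx, Dhx, Cpsf and Thoc families), 91 in all, had a pooled ratio of 1.23 (1.13 to 1.34) at percentile 100 of random lists, which argues against chance membership. A regional difference and a single deciding gene are argued against by a ratio of 0.980 (0.903 to 1.07) in the flanks of the list and by a lowest ratio of 1.3 ± 0.104 with any 1 gene left out. No list was matched on expression, promoter type or base composition, so a bias toward broadly expressed genes could give such ratios, and the housekeeping list, with 1.09, was at percentile 74.6 matched on flank reads but 94.96 matched on background.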
